A study of Oryza sativa with 6 samples.

How the data were processed

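The data are 6 Agilent two-colour rice arrays, 3 from copper-treated and 3 from cadmium-treated roots, each hybridised with Cy5-labelled cRNA of treated roots and Cy3-labelled cRNA of water-control roots, per the labels' protocols. The dyes were never swapped, so an effect of the dye on a given probe cannot be told apart from an effect of a metal against the control. Groups and replicate numbers come from the sample titles. The labels describe the replicates as biological.

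The spot intensity values in the scanner files were deposited as Feature Extraction 10.7.1.1 wrote them, per the file headers: the median brightness of each spot and of its local background in each channel, not normalized. The processed intensity in the same files was background-subtracted, spatially detrended and dye-normalized by that program, per the file headers, and the deposited log10 ratio is the ratio of these processed signals, Cy5 over Cy3. The authors' series table holds log2 ratios for 42475 probes. Set against the log2 of the scanner's ratio, its columns had slopes between 1.000 and 1.001 and correlations between 0.988 and 1.000, so the scale is log2 and the direction treated over control. What centring or filtering the authors applied is not given in the sources used here. The medians of its columns were -0.067, -0.161 and -0.191 for copper 1 to 3 and -0.050, -0.145 and -0.080 for cadmium 1 to 3.

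Each array held 45151 spots, of which 43734 were not control spots, on 42477 probes. Background was corrected with normexp (offset 50) on the median signals, since the design called for mean signals and the scanner tables used here hold medians. Each array was normalized by loess, with control spots and spots marked as non-uniform or population outliers given no weight in the curve, and the marked spots were then left out. Such spots were 2.85% of those on copper 1, 1.45% on cadmium 1 and at most 0.16% on the others. Spots of a probe were averaged. Probes were kept if well above background on all 3 arrays of at least 1 metal in at least 1 channel, with at least 2 values per metal, which left 33695 probes. For each gene the probe of highest mean intensity was tested. Of loci with more than 1 called probe, 18 of 2413 with copper and 35 of 1717 with cadmium had probes called in opposite directions, and 8 of 585 between the metals.

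Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), all 6 arrays in one model with a coefficient per metal. Tests were two-sided, with Benjamini-Hochberg adjustment over the 23416 genes and a threshold of 0.05. Fold changes at least 2-fold mean an absolute log2 change of at least 1. The filter keeps dim probes that only 1 metal lights up, and loess assumes that most genes do not change. Where a probe was not well above background in the control channel on any array of a metal, no fold against the control is given.

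The array files pair microRNA probes with precursor names and give other probes a locus number. None of these numbers or accessions matched the reference table of assembly ASM3414082v1 (0 and 0 matches), so protein-coding genes are not named. The 54 gene lists fixed before the data were examined are patterns in gene names and descriptions, and 0 of them matched a gene, so they could not be tested, and the lists for metallothioneins, copper homeostasis and phytochelatin synthesis gave no members. In their place 12 lists were read from the probe names after these had been seen: all microRNA precursors, 8 families with at least 5 members that had a value on every array and 3 classes given in the probe names (MRNA, COMBINER_EST and COMBINER), whose meaning is not stated in the sources used here. The miR171 family has 6 measured members, of which fewer than 5 had a value on every array, and was not tested as a list. The 12 lists were tested with camera (preset correlation 0.01), with estimated correlation and with fry, on 22601 genes with a value on every array. The array carries 510 probes for 169 precursor names, on the mature sequence and on both flanks. They read labelled cRNA of long RNA, not mature microRNA.

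The rule for named genes, fixed before the data were examined, took per comparison the 8 largest rises and the 8 largest falls past the threshold, with the same sign on all 3 arrays (between the metals: no overlap of the 3 copper and 3 cadmium ratios), among genes whose name in the files says what they are. Here that left microRNA precursors. The 2 loci with the largest rise and fall per comparison are given by number. Loci that bound a chromosome window were chosen after their values were seen.

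Replicate numbers are shared by the groups in the titles. Deviations of same-numbered copper and cadmium arrays from their group means correlated across genes at 0.37, 0.24 and 0.27 for numbers 1, 2 and 3, all above 0.1, which was the rule for taking the numbers as pairs, and a fit with the number as a block was run. The values for 2 and 3 are not particular to the number, since copper 2 with cadmium 3 gave 0.23 and copper 3 with cadmium 2 gave 0.18. Copper 2, copper 3, cadmium 2 and cadmium 3 lay on 1 slide scanned on 1 day, and copper 1 and cadmium 1 each on a slide of its own. Copper 2 and 3 were nearly identical. On 237 probes with replicate spots, their ratios differed by 0.146 (root mean square, log2), where spot noise within an array predicts 0.118. Cadmium 2 and 3 differed by 0.195, where spot noise predicts 0.13. Across genes the ratios of cadmium 2 and 3 correlated at 0.95, against 0.96 for copper 2 and 3, and no mean of that cadmium pair was tried. Copper 2 and 3 were kept as 2 arrays, as the labels describe them. The comparison does not show that they are independent, since technical replicates labelled and hybridised separately would also differ by more than spot noise, so their mean was added as an alternative.

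Shared controls were simulated with 100 draws. Neighbouring loci were tested by 10000 shuffles of the calls within chromosomes. The steps were checked on simulated arrays. Of 23416 genes, 100% of the 80 genes set to a 2-fold change with copper and 100% of the 40 set to 4-fold were recovered, 47.5% of the 80 set to a log2 change of 0.5, and 13 of 23216 unchanged genes were called. For the difference between the metals, 89.5% of 38 genes set to 2-fold were recovered and 10.0% of 30 set to a log2 difference of 0.5. The simulated noise was independent between arrays, no probe had a dye effect, and 23216 of 23416 genes were unchanged with copper. The data may differ on each point, so this check tests the steps and not the rate of false calls in the data. Alternatives covered background correction, normalization within and between arrays, the filter, outlier spots, the choice of probe, the variance model and the arrays in the fit. Others used the replicate block, only the arrays of the slide that holds both metals, or the slide as a random block. The authors' values, the thresholds and each array left out were also tried. Figures were drawn with matplotlib 3.10.9.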

Results

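Transcript levels were measured in roots of 6-day-old rice seedlings (Oryza sativa, cultivar TN-67) exposed to 5 µM copper or to 25 µM cadmium, on 3 two-colour oligonucleotide arrays per metal. On each of the 6 arrays the RNA of metal-treated roots carried the red dye Cy5 and the RNA of roots kept in water carried the green dye Cy3, so each array gave the ratio of treated to control roots for every probe. The labels call the 3 arrays of a metal biological replicates. The time of exposure is not given in the labels used here. Between 77.0% and 82.3% of the probes were well above background in the Cy5 channel of an array, and between 75.6% and 81.2% in the Cy3 channel, and no spot was saturated. After the filter on dim probes, 23416 genes were compared, of which 23287 were annotated rice loci and 129 were microRNA precursors. The number of arrays limits the precision. The median standard error of a gene's log2 change was 0.094 for either metal against the control and 0.133 for the difference between the metals. These standard errors treat the arrays as independent, although arrays of both metals shared a slide. With the slide as a random block, the estimated correlation among arrays of the same slide was 0.664 (22601 genes). That fit called fewer genes against the control and more between the metals, as given below. The standard errors against the control may therefore be too small. The files identify protein-coding loci by locus number and do not pair these numbers with gene names, so only the microRNA precursors are given by name.

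The first comparison asked which transcripts changed in roots given copper. Copper raised 5958 genes and lowered 4087 of the 23416 measured (limma, adjusted p under 0.05), and most of the large changes were rises. Of 1834 genes that changed at least 2-fold, 1742 rose and 92 fell. With the scanner's processed signals, 2394 rose and 907 fell at least 2-fold, and with these centred on their median 2730 and 560. The count of falls was 182 without copper replicate 1, 60 without copper replicate 3 and 183 with only the arrays of the slide that holds both metals. All 499 genes that changed at least 4-fold here rose, 157 of them at least 8-fold and 32 at least 16-fold. The highest rises were those of Os03g0267000 on chromosome 3, with a log2 change of 5.41 ± 0.20 (SE, n = 3, adjusted p = 2.03e-06), and of Os08g0277200 on chromosome 8, with 5.23 ± 0.33 (SE, n = 3, adjusted p = 2.11e-05). The control signal of Os03g0267000 was well above background on 2 of the 3 copper arrays and that of Os08g0277200 on 1. The deepest falls reached -1.71 ± 0.23 (SE) in Os07g0120000 and -1.70 ± 0.10 (SE) in Os04g0449200. The split of calls into rises and falls moved with the scaling of the arrays. With the scanner's own processed signals, whose median over these genes was -0.13 on the log2 scale, 4925 genes were higher and 7378 lower, where 59.3% of the calls were higher here. Of the arrays, 4 lay on 1 slide, 2 of each metal, and with these 4 alone 13526 genes were called for copper. That fit holds no slide term, since against the control a slide effect cannot be told apart from that of the metal. The count is therefore not adjusted for slide. The spread in that fit comes only from copper 2 against 3 and cadmium 2 against 3, whose ratios correlated at 0.96 and 0.95, so the count may be too high. With the slide as a random block 8272 genes were called. Copper replicates 2 and 3 were closer to each other than any other pair of arrays, and the count of calls was 6592 without copper replicate 2, 5762 without copper replicate 3 and 6243 with these arrays averaged and counted as 1.

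MicroRNA precursors, the longer transcripts from which microRNAs are cut, were measured for 129 names. With copper 45 rose, 3 fell and 81 did not pass the test, with a median log2 change of 0.21. The median lay above those of all 10000 random lists of genes matched on intensity, of which 95% lay between -0.04 and 0.11. The lists were matched on intensity alone. As the dyes were not swapped, an effect of the dye on the microRNA probes cannot be told apart from that of copper. The median stayed above 0 under all 8 scalings tried, between 0.18 and 0.53. Here and below these are not 8 separate checks. One scaling acts on intensities and leaves the log2 ratios unchanged, and the authors' values follow the scanner's processed signals. The list of all precursors was higher by camera with a preset correlation of 0.01 (adjusted p = 0.00225), a call that was lost at adjusted p = 0.496 with an estimated correlation. The number of precursors that rose was 13 without copper replicate 2, 14 without copper replicate 3 and 25 with median centring in place of loess. The changes were small. The largest rise was that of osa-miR416, with a log2 ratio of 0.75 ± 0.32 (SD, n = 3, adjusted p = 0.0245). The precursors osa-miR156e, osa-miR166h and osa-miR168b rose by 0.64 ± 0.16, 0.63 ± 0.16 and 0.62 ± 0.05 (SD, n = 3 each). MiR156 is known to restrain SPL transcription factors, miR166 HD-ZIP III transcription factors, and miR168 the silencing protein AGO1. The other rises among those named were in osa-miR164d, osa-miR398b, osa-miR442 and osa-miR166c, with log2 ratios from 0.47 to 0.54. A second kept probe of osa-miR442 went the other way. The second kept probes of osa-miR156e and osa-miR166h (0.31 and 0.18) were higher without passing the test. The 2 other kept probes of osa-miR166c (0.03 and 0.26) did not pass either. Those of osa-miR168b, osa-miR164d and osa-miR398b passed. The precursors that fell were osa-miR171h, with -0.69 ± 0.31 (SD, n = 3, adjusted p = 0.0157), osa-miR446, with -0.33 ± 0.06, and osa-miR396b, with -0.26 ± 0.10. MiR171 is known to act on GRAS transcription factors and miR396 on growth-regulating factors. The calls of osa-miR416, osa-miR442 and osa-miR396b were lost without any 1 of the copper arrays (adjusted p between 0.0527 and 0.136), those of osa-miR166c, osa-miR171h and osa-miR446 without copper replicate 2 or 3 (between 0.0675 and 0.104), and that of osa-miR442 also without cadmium replicate 2 (0.0588). Over all 24 alternatives the call was lost in 9 for osa-miR442, which fell to 0.18 (adjusted p = 0.297) with the mean of its kept probes, in 6 for osa-miR396b, in 4 each for osa-miR416, osa-miR166c and osa-miR446, and in 3 for osa-miR171h. The value ranged from -1.15 to -0.56 for osa-miR171h, from -0.71 to -0.25 for osa-miR446 and from -0.48 to -0.19 for osa-miR396b.

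By family, 6 of 11 measured miR156 precursors rose with copper (median log2 change 0.34), 16 of 22 miR395 precursors (0.29), 5 of 13 miR166 precursors (0.20) and 4 of 6 miR164 precursors (0.31). Only the miR156 and miR395 families passed camera among the 8 families tested (adjusted p = 0.0458 and 0.0026), and neither did so with an estimated correlation (adjusted p = 0.496 and 0.538). The other 6 families had adjusted p between 0.132 and 0.432, and the median of each of the 8 families stayed above 0 under all 8 scalings. These families were read from the probe names after the names had been seen. The probes on the mature miR395 sequence give nearly the same values for many precursors, which share that sequence, and are best read as 1 signal. Precursors read by these probes count separately in the 45 that rose with copper. The random matched lists do not allow for such repeats. Families linked to copper were also looked up, chosen after their values were seen. Of these, osa-miR398b rose by 0.52 ± 0.22 (SD) and osa-miR408 had a log2 ratio of 0.40 ± 0.08 (adjusted p = 0.00736). A second kept probe of osa-miR408 gave 0.09 with copper (adjusted p = 0.684) and 0.20 with cadmium (adjusted p = 0.359). No direction was set beforehand for these families, so the rises are not read as a known response to copper. The values of osa-miR528, 0.42 ± 0.44 (adjusted p = 0.107), and osa-miR397b, 0.14 ± 0.34 (adjusted p = 0.406), did not pass the test. With cadmium the log2 ratio of osa-miR398b was 0.48 ± 0.02 (SD, adjusted p = 0.00607), with a control signal well above background on 1 of the 3 arrays, and that of osa-miR408 0.60 ± 0.17 (SD, adjusted p = 0.00165). The differences between the metals, 0.04 and -0.20, did not pass (adjusted p = 0.876 and 0.354).

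**Figure D1:**
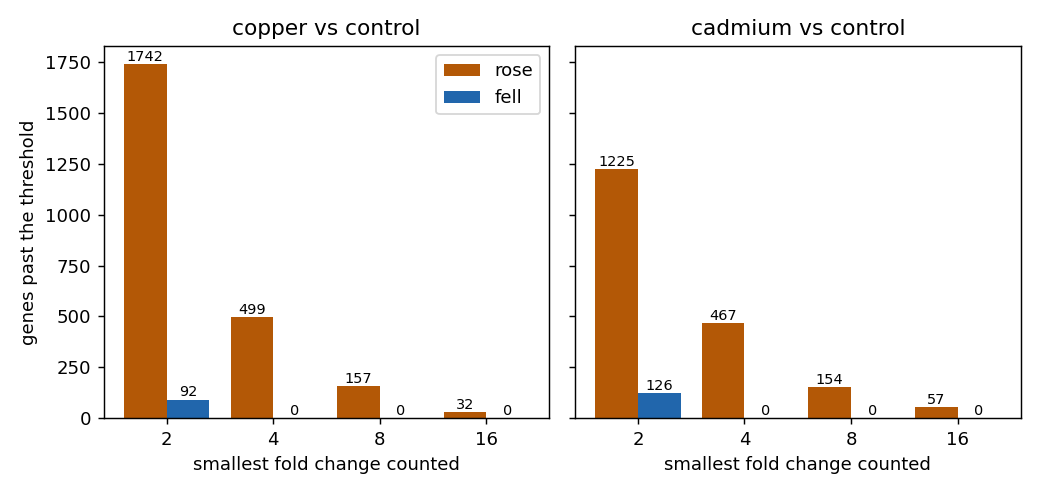
Number of genes past the threshold (vertical axis) that rose or fell by at least 2-, 4-, 8- or 16-fold (horizontal axis) with copper (left) and cadmium (right) against the water control. At 2-fold, 1742 genes rose and 92 fell with copper, and 1225 rose and 126 fell with cadmium.

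The second comparison asked the same of cadmium. Cadmium raised 4929 genes and lowered 3031, and here too most of the large changes were rises. Of 1351 genes that changed at least 2-fold, 1225 rose and 126 fell. With the scanner's processed signals, 1777 rose and 756 fell at least 2-fold, and with these centred on their median 1950 and 573. All 467 genes that changed at least 4-fold here rose, and 57 of these rose at least 16-fold, against 32 with copper. The highest rises were in Os03g0267000, with a log2 change of 7.47 ± 0.20 (SE, n = 3, adjusted p = 8.16e-07), and in the neighbouring locus Os03g0266900, with 6.54 ± 0.20 (SE, n = 3, adjusted p = 1.38e-06). The deepest falls were -1.87 ± 0.18 (SE) in Os05g0217700 and -1.75 ± 0.15 (SE) in Os01g0703300. With the scanner's processed signals, 41.7% of the cadmium calls were higher against 61.9% here. The count of 7960 calls was 11242 with only the arrays of the slide that holds both metals and 6432 with the slide as a random block. It was 4491 without cadmium replicate 2 and 5122 without cadmium replicate 3. The count with the arrays of that slide alone has the limits given for copper.

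Of the 129 microRNA precursors, 62 rose with cadmium, 2 fell and 65 did not pass the test, with a median log2 change of 0.28. The median again lay above those of all 10000 matched lists, of which 95% lay between -0.05 and 0.08, and stayed between 0.26 and 0.59 under all 8 scalings. An effect of the dye on the microRNA probes is again not excluded. Between the metals, where a constant dye effect cancels, the median difference was -0.06 (camera adjusted p = 0.165). The number of precursors that rose was 33 without cadmium replicate 2 and also 33 with median centring in place of loess. Camera gave adjusted p = 2.17e-07 for the whole list, and adjusted p = 0.305 with an estimated correlation. The largest rise was that of osa-miR418, with a log2 ratio of 2.00 ± 0.88 (SD, n = 3, adjusted p = 0.00161). Its control signal was well above background on 1 of the 3 cadmium arrays, and its value ranged from 1.55 to 4.67 over the alternatives, highest with the scanner's processed signals centred on their median. Rises followed in osa-miR416 (1.03 ± 0.61), osa-miR169i (0.80 ± 0.53), osa-miR442 (0.73 ± 0.48) and osa-miR156d (0.67 ± 0.50). The precursor osa-miR156e rose by 0.66 ± 0.16 and osa-miR169j by 0.61 ± 0.12. For osa-miR169j the control signal was well above background on 1 of the 3 arrays, and the value ranged from 0.5 to 1.65 over the alternatives. The call of osa-miR156d was lost without cadmium replicate 1, cadmium replicate 2 or copper replicate 2 (adjusted p = 0.148, 0.113 and 0.0511), and in 4 of all 24 alternatives. Second kept probes of osa-miR156d, osa-miR156e and osa-miR442 gave 0.07, 0.38 and 0.27 and did not pass. Those of osa-miR418 and osa-miR169i passed. Without cadmium replicate 1 the log2 ratios were 0.68 for osa-miR416, 0.49 for osa-miR169i, 0.46 for osa-miR442 and 0.40 for osa-miR156d. MiR169 is known to act on NF-YA transcription factors. The control signal of osa-miR395o was not well above background on any cadmium array, so no fold is given for its rise (adjusted p = 0.0011), which was lost with no filter on dim probes, where its probe on the mature sequence was tested (log2 change 0.21, adjusted p = 0.0538). Both precursors that fell belong to the miR171 family. They were osa-miR171h, with -1.31 ± 0.46 (SD, n = 3, adjusted p = 0.00126), and osa-miR171f, with -0.74 ± 0.25 (SD, n = 3, adjusted p = 0.00157). The family did not move as one. Of its 6 measured precursors, osa-miR171b, osa-miR171c and osa-miR171e rose with cadmium, with log2 changes of 0.39, 0.44 and 0.21, and osa-miR171g (0.07) did not pass, and these 4 were looked up after the values of the others were seen.

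MiR395 is known to rise when sulfate is short and to act on sulfate transporters and ATP sulfurylases. With cadmium, 20 of its 22 measured precursors rose, with a median log2 change of 0.47 (camera adjusted p = 2.17e-07, and adjusted p = 0.305 with an estimated correlation). Most of the 22 were read by the probe on the shared mature sequence, so most of these rises are best read as 1 signal. The correlation estimated within the family was 0.617. These rises also count separately in the 62 precursors that rose with cadmium. The miR169 family had 7 of 12 members higher (median 0.27), the miR156 family 5 of 11 (0.26), the miR166 family 6 of 13 (0.18), the miR164 family 4 of 6 (0.33) and the miR160 family 3 of 6 (0.29). These 5 families passed camera with the preset correlation, at adjusted p between 0.0207 and 0.0457, and none did with an estimated correlation, at adjusted p between 0.305 and 0.411. The miR399 and miR439 families did not pass camera (adjusted p = 0.399 and 0.117). They passed fry (adjusted p = 0.00339 and 0.0263), which does not set a list against the other genes. The median of each of the 8 families stayed above 0 under all 8 scalings.

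**Figure D2:**
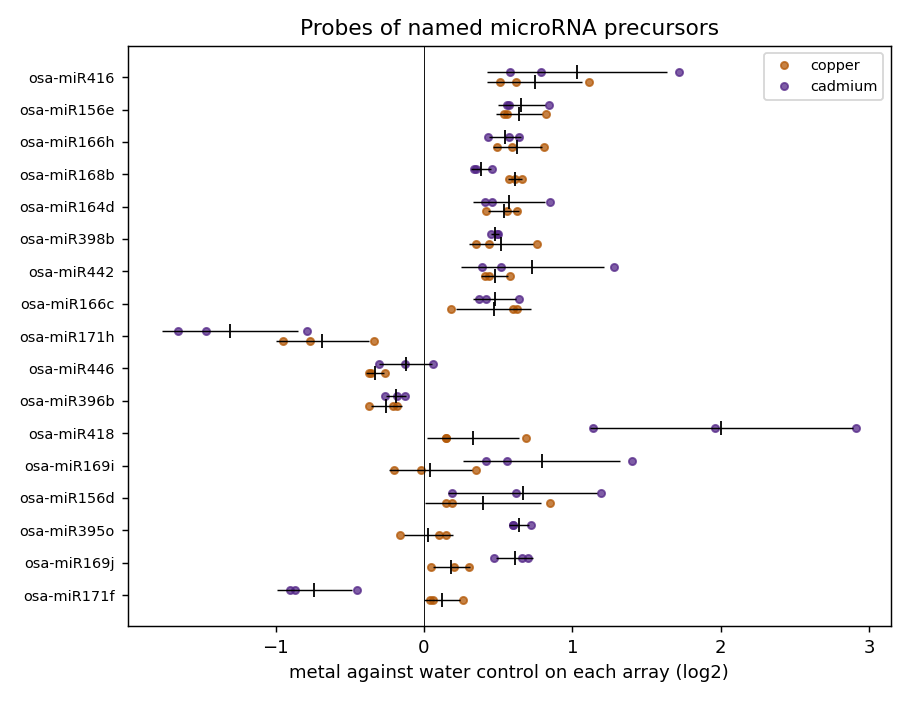
Log2 ratio of metal-treated to control roots (horizontal axis) for the probe of each named microRNA precursor (vertical axis). Points are single arrays (3 copper, 3 cadmium), the vertical tick is their mean and the bar is 1 SD. The precursor osa-miR171f lies at -0.74 with cadmium and 0.12 with copper.

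Copper and cadmium changed many genes in the same direction. Of the genes that rose, 3479 rose with both metals, where independent lists would share 1254.1, and of the genes that fell, 1692 fell with both, where independent lists would share 529.0. With the scanner's processed signals 2917 rose and 3917 fell with both, so which direction is shared by more genes turns with the scaling. The shared falls numbered 1001 without copper replicate 2, 845 without copper replicate 3, 849 without cadmium replicate 2 and 941 without cadmium replicate 3. With only the arrays of the slide that holds both metals they numbered 2962. Among changes of at least 2-fold, 826 genes rose with both (91.1 for independent lists) and 35 fell with both. Opposite calls were few, with 103 genes higher with copper and lower with cadmium and 63 the other way. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.713 (Spearman rho = 0.688), with a covariance of 0.256. The series lists 3 control samples for the 6 arrays, so the metals may share control RNA. In 100 simulated draws with no effect, controls that supplied all of the spread between arrays gave a mean covariance of 0.018 and a mean of 2.92 shared calls. The simulated correlation was then 1, so the observed correlation alone does not exceed what shared controls can give. Controls that supplied 50% of the spread gave a correlation of 0.50, a covariance of 0.00897 and 0.03 shared calls. The observed covariance exceeded the larger simulated value by 0.238. The simulated spread was that between arrays. A control effect common to all arrays adds nothing to that spread, and one common to a slide was not simulated. The estimated correlation among arrays of the same slide was 0.664. The simulated covariance may therefore be too small, and the excess does not exclude shared controls as a source of the overlap. Dye effects common to all arrays were not part of the simulation and cannot be separated from the overlap.

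**Figure D3:**
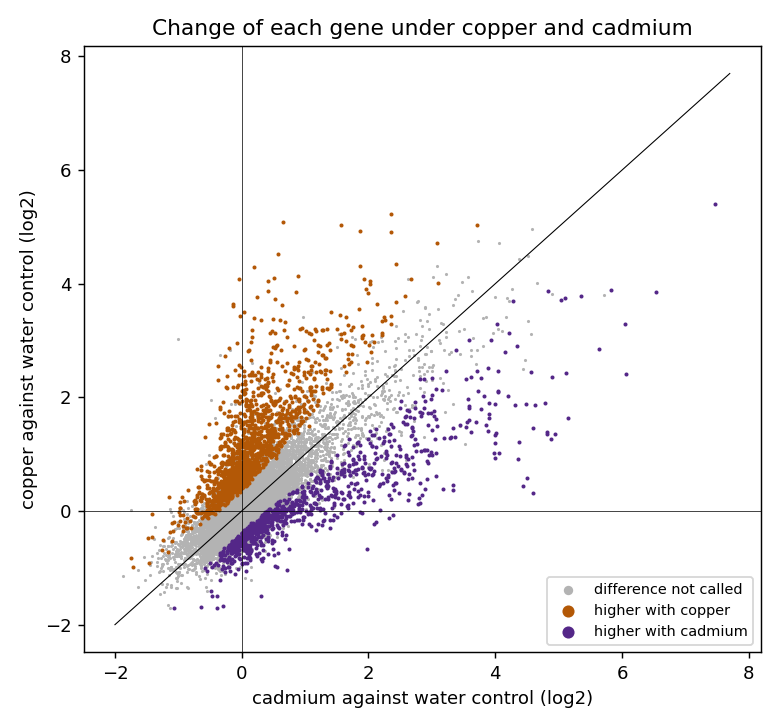
Log2 change of each of 23416 genes with copper (vertical axis) against its change with cadmium (horizontal axis), with the line of equal change. Coloured points differ between the metals past the threshold, 1538 higher with copper and 953 higher with cadmium.

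The third comparison set the metals against each other, where a dye effect constant over the arrays cancels. Each metal was given at 1 dose, 5 µM copper or 25 µM cadmium. A difference between the metals therefore cannot be told apart from one of dose or strength of exposure. In all, 2491 genes differed, with 1538 higher with copper and 953 higher with cadmium, and 896 differed at least 2-fold (583 and 313). Of the genes higher with copper, 1395 had risen with copper against the control, and of those higher with cadmium, 657 had risen with cadmium. The metals also differed within the shared rise, since 439 genes rose with both and more with copper, and 321 rose with both and more with cadmium. The largest differences towards copper were in Os09g0417600 (4.42 ± 0.43 log2, SE, adjusted p = 0.00102) and Os10g0503300 (4.12 ± 0.30, adjusted p = 0.000324). Towards cadmium they were in Os10g0542700 (-4.28 ± 0.42, adjusted p = 0.00101) and Os09g0492900 (-4.00 ± 0.19, adjusted p = 0.000118). The control signals of Os10g0503300, Os10g0542700 and Os09g0492900 were well above background on 3, 1 and 2 of the 6 arrays. With the replicate number as a block 3806 genes differed, 2223 higher with copper and 1583 higher with cadmium. One slide held 2 arrays of each metal, and within it, which is also the fit with the slide as a block, 6077 genes differed. The spread in that fit comes only from copper 2 against 3 and cadmium 2 against 3, whose ratios correlated at 0.96 and 0.95. Its count may therefore be too high. With the slide as a random block 5759 differed. Leaving out copper replicate 2, copper replicate 3, cadmium replicate 2 or cadmium replicate 3 gave 1257, 1252, 1282 and 1350 genes, and 1262 genes differed with copper replicates 2 and 3 averaged as 1 array.

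Between the metals, 3 of the 129 microRNA precursors passed the test. The precursor osa-miR171f was higher with copper by 0.86 ± 0.15 (SE, adjusted p = 0.0101), as its log2 ratio was 0.12 ± 0.12 (SD, n = 3) with copper and -0.74 ± 0.25 (SD, n = 3) with cadmium. The precursors osa-miR418 and osa-miR395o were higher with cadmium, with differences of -1.67 ± 0.40 (SE, adjusted p = 0.0372) and -0.61 ± 0.12 (SE, adjusted p = 0.0167). The control signal of osa-miR395o was well above background on 0 of the 6 arrays, and its Cy5 signal on 4. The call of osa-miR171f was lost without copper replicate 3 (adjusted p = 0.0501), that of osa-miR418 without copper replicate 2, copper replicate 3 or cadmium replicate 2 (0.128, 0.128 and 0.107), and that of osa-miR395o without copper replicate 2, cadmium replicate 2 or cadmium replicate 3 (0.0541, 0.0615 and 0.0557). With no filter on dim probes the probe of osa-miR395o on the mature sequence was tested, and its difference was -0.14 (adjusted p = 0.486). When every probe was tested with limma, second kept probes on the other flank passed. They gave 0.68 for osa-miR171f, -1.42 for osa-miR418 and -0.58 for osa-miR395o (adjusted p = 0.0335, 0.00143 and 0.0316). These probes read the same arrays and are not further replicates. Over all alternatives the call was lost in 3 of 23 for osa-miR171f, in 5 of 22 for osa-miR418 and in 4 of 22 for osa-miR395o. The difference ranged from -3.19 to -1.22 for osa-miR418 and from -2.83 to -0.14 for osa-miR395o. For the miR395 family the median difference was -0.18 (camera adjusted p = 0.0158), which was lost with an estimated correlation (adjusted p = 0.846) and with fry (adjusted p = 0.41), and reached adjusted p = 0.227 without copper replicate 1 and 0.239 without cadmium replicate 1. The list of all precursors did not pass camera (median -0.06, adjusted p = 0.165), although its median lay at percentile 0.41 of the 10000 matched lists, of which 95% lay between -0.04 and 0.06. It passed without cadmium replicate 3 (adjusted p = 0.0106). The other 7 families had adjusted p between 0.165 and 0.877.

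Genes that responded lay next to each other more often than in shuffled orders. Rice locus numbers run in order along each chromosome. Among loci raised at least 2-fold by copper there were 257 adjacent measured pairs, against a mean of 130.8 in 10000 shuffles within chromosomes. Cadmium gave 160 pairs against 64.1, loci higher with copper than with cadmium 55 pairs against 14.9, and loci higher with cadmium 21 pairs against 4.2. Each of these 4 counts had permutation p = 1e-04, the smallest that the shuffles can give. Among loci lowered at least 2-fold, copper gave 3 pairs against 0.4 (permutation p = 0.0072) and cadmium 0 against 0.6. On chromosome 11, between Os11g0227600 and Os11g0229500, 7 of 10 measured loci were at least 2-fold higher with copper than with cadmium. The median difference of these 7 was 1.55 on the log2 scale. On chromosome 10, between Os10g0525400 and Os10g0528100, 5 of 10 were at least 2-fold lower with copper than with cadmium, and the median difference of these 5 was -2.69. These windows were chosen after their values were seen. No chromosome as a whole held more or fewer of the at least 2-fold calls than the others in 72 Fisher's exact tests, the lowest adjusted p being 0.0884, for chromosome 11 in loci higher with copper than with cadmium.

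**Figure D4:**
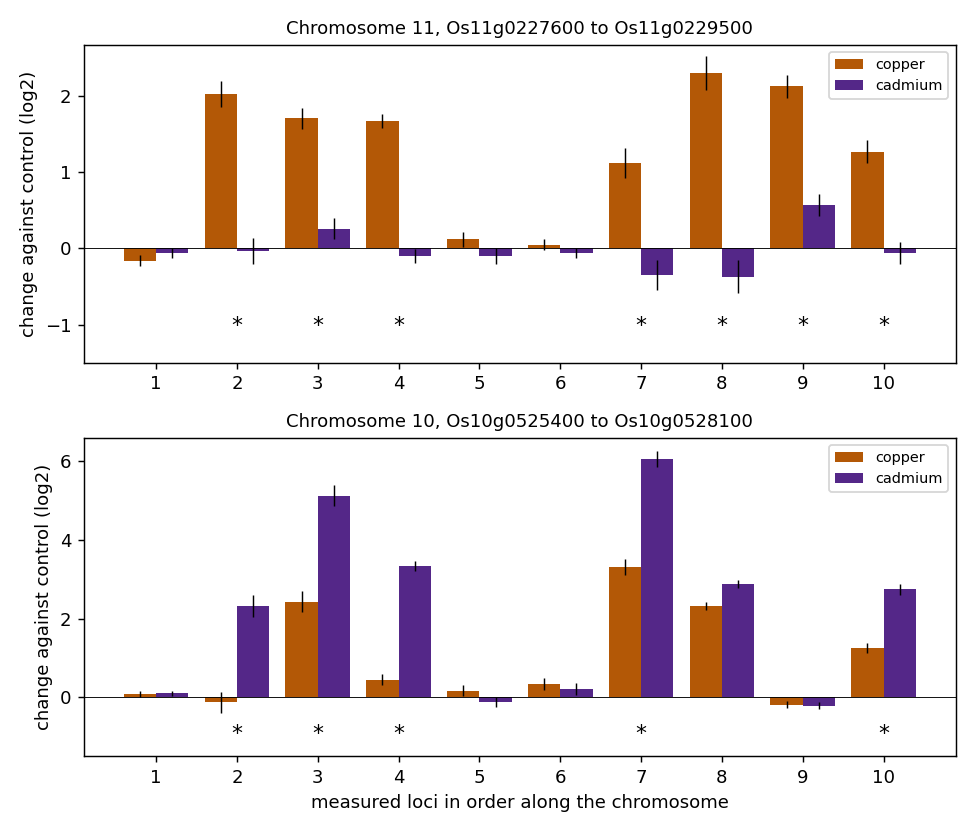
Log2 change against the control (vertical axis) of 10 neighbouring measured loci (horizontal axis) on chromosome 11 (top) and chromosome 10 (bottom), with copper and cadmium side by side. Bars are fitted means of 3 arrays, error lines are 1 SE, and asterisks mark loci that differ at least 2-fold between the metals, 7 in the upper window and 5 in the lower.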

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

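The tests of normalization and of the slide or scan day were chosen after the results were seen.

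Copper and cadmium differed, by the limma contrast between the metals, in several of the genes named above. Differences are copper minus cadmium on the log2 scale. The precursor osa-miR171f differed by 0.86 (adjusted p = 0.0101), osa-miR418 by -1.67 (adjusted p = 0.0372) and osa-miR395o by -0.61 (adjusted p = 0.0167). For osa-miR395o the control was well above background on 0 of the 6 arrays, so the size of its difference is uncertain, and its probe on the mature sequence gave -0.14 (adjusted p = 0.486). The median of the miR395 family differed by -0.18. Among loci, Os09g0417600 differed by 4.42, Os10g0503300 by 4.12, Os08g0277200 by 2.87 and Os01g0703300 by 0.93. Lower with copper were Os10g0542700 by -4.28, Os09g0492900 by -4.00, Os03g0266900 by -2.68, Os03g0267000 by -2.07 and Os04g0449200 by -1.31.

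Some probes that the array's design lists as controls, and that no comparison used, gave a signal well above background in treated roots on all 6 arrays and a higher value than the control roots on each. The mean log2 ratio was 1.39 for POsControl0004 and 0.42 for POsControl0005, both listed under rice genome, and 0.32 for POsControl0027, listed under random sequence. These probes were picked for such values, and others, such as POsControl0001 and POsControl0030, changed sign between arrays. The median of the 24 rice genome controls was 0.02 with copper and 0.01 with cadmium, and of the 12 random sequence controls 0.02 and 0.04. For POsControl0004 the mean was 1.39 with either metal. An effect of the dye on these probes cannot be told apart from one of the metals.

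Rises outnumbered falls among changes of at least 2-fold. A floor of the control signal, which would leave dim genes no room to fall, was set against genes in the brightest of 3 equal bins by control signal. There 84.1% of 422 such copper changes were rises (95% exact binomial interval 80.3 to 87.5), which argues against a floor as the whole cause. A dye effect shared by all arrays was set against genes whose cadmium change lay within 0.25 of 0. Of 281 such copper changes 97.5% were rises, so the excess was also present where the cadmium ratio shows no such effect. That choice leaves out probes with a large shared dye effect. It does not bear on the other genes, such as the 826 that rose at least 2-fold with both metals, where a dye effect stays open. Normalization stays open in part, since the share of rises was 95.0% here and 72.5% with the scanner's processed signals, and a biological excess of rises was not tested apart from it.

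Arrays of replicate 1 stood apart from replicates 2 and 3 in both channels. The Cy3 channels of copper 1 and cadmium 1, which were on different slides scanned on different days, differed by 0.404 (root mean square, log2), and the smallest difference from either to replicates 2 and 3 was 0.891. As all arrays of replicates 2 and 3 lay on 1 slide scanned on 1 day, an effect of that slide or day would give the same values, so slide, scan day and replicate cannot be told apart. A separate batch of seedlings or of labelling for replicate 1 was not tested.

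The splits of the arrays are too few for a share under 0.05. For copper against cadmium, 1 of the 10 splits into 3 and 3, the real one, gave 2491 genes, and the highest other gave 0. Reversing the sign of 1 array gave at most 6 genes for copper against 10045, and at most 4 for cadmium against 7960, with the real signs the 1 of 4 that gave as many. Reversing an array or mixing the metals turns any effect shared by the arrays of a metal into spread, whatever its source. Low counts follow from that and do not tell the metal from other sources.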

How the results depend on the processing

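The slide as a random block, the average of copper replicates 2 and 3 and the microRNA lists were chosen after seeing the data. The correlation of copper and cadmium changes moved by less than 1 SD between array pairs under every alternative (0.694 to 0.735). Counts for either metal against the control stayed within 1.5 times under every background, normalization, filter, probe, variance and block setting. The replicate block gave 12156 genes for copper and 10333 for cadmium, and the slide as a random block 8272 and 6432. The arrays of the slide that holds both metals gave 13526 and 11242 on their own, with no slide term in the fit. The spread there rests on a close pair of arrays per metal, so these counts, and the 6077 below, may be too high. At adjusted p under 0.01 the counts were 6102 for copper, 4137 for cadmium and 1032 between the metals, and with a log2 change of at least 1 they were 1834, 1351 and 896, as stricter thresholds must give. With copper replicates 2 and 3 averaged, 6243 genes were called for copper and 1262 between the metals. The count between the metals was 3806 with the replicate block, 6077 within the slide that holds both metals and 5759 with the slide as a random block. Leaving out 1 array at a time gave 5762 to 11657 genes for copper, 4491 to 9008 for cadmium and 1252 to 3038 between the metals, some above and some below the count with all arrays.

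With an estimated correlation, camera gave adjusted p = 0.496 and 0.305 for all microRNA precursors with copper and cadmium, and 0.538, 0.305 and 0.846 for the miR395 family with copper, cadmium and between the metals. That last difference was also lost with fry (0.41), processed signals (0.131) and median centring (0.0505), and ranged from 0.00222 to 0.239 with 1 array left out. All precursors differed between the metals with median centring (0.0265), and their adjusted p ranged from 0.0106 to 0.702 with 1 array left out. With fry, all precursors and the miR395 family passed with copper (adjusted p = 0.00827 and 0.0162) and with cadmium (0.00339 each). The causes of these shifts were not tested. Of 36 named values, 25 kept their call in every alternative, 11 lost it in at least 1 and 0 reversed. The replicate block ended none of these calls and none of the calls of all precursors or of the miR395 family. Sizes moved too, by over 1.5 times in at least 1 alternative for 18 of the 36 values. Of 49 such fits, 35 used the scanner's processed signals or the authors' values, and all 35 gave the larger size. Outside these settings 9 values moved so. The planned gene lists matched no gene and were not run.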

Other observations

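The tests of probe distance and of probes sharing a transcript were set before their results were seen. Those of shuffled orders, and the miR395 flank comparison and the probe classes, were chosen after the values were seen.

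Probes on the flanks of miR395 precursors lie outside the shared mature sequence. Of 46 flank probes, counted with no filter on dim probes because the filter favours probes that 1 metal lights up, 22 rose with cadmium and 1 with copper, and none fell, with median log2 changes of 0.27 and 0.01. The difference between the metals itself passed for 5 of them. Of 294 flank probes of other precursors, 50 rose and 6 fell with cadmium, 42 rose and 11 fell with copper, and 3 were lower with copper than with cadmium. On the mature sequence, 19 of 23 probes rose with cadmium and 16 with copper, with medians of 0.44 and 0.29. The difference between flank and mature probes was not tested. The flank probes are dim, and among the 20 kept by the filter the control was well above background on all cadmium arrays for 1, and the copper-treated signal on all copper arrays for 1, which limits what could be called with copper.

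Genes were also compared by the class that their probe names carry, whose meaning the sources used here do not give. The median log2 change of the 1403 genes of class COMBINER was 0.15 with copper and 0.10 with cadmium, that of the 4785 genes of class COMBINER_EST 0.08 with both, and that of the 17098 genes of class MRNA -0.01 with both. With the scanner's processed signals, whose median over all genes was -0.13 with copper and -0.11 with cadmium, the medians were 0.09 and 0.04 for COMBINER, -0.04 and -0.01 for COMBINER_EST, and -0.17 and -0.14 for MRNA. The class COMBINER passed camera for copper (adjusted p = 0.0185) and cadmium (adjusted p = 0.0337), and lost both calls with an estimated correlation (adjusted p = 0.496 and 0.305). The class MRNA was lower by camera with cadmium (adjusted p = 0.0261, and 0.305 with an estimated correlation), while its mean was 0.09 and fry placed it higher. With copper its adjusted p was 0.0993 and its mean 0.13. The class COMBINER_EST did not pass with copper (adjusted p = 0.27) or cadmium (0.0601). Between the metals the 3 classes had adjusted p of 0.801 or 0.806.

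Neighbouring loci rose together, with 257 adjacent pairs raised at least 2-fold by copper and at most 183 in any of 10000 shuffled orders, which argues against a chance order. The probes of these pairs lay at 97.2% of the distance of random pairs on the array (95% range 85.4 to 111.3), which argues against neighbouring spots. A single transcript read by both probes stays open. In 57.6% of the 257 pairs the copper changes differed by more than 2 standard errors, but a probe that reads its own transcript and part of a similar neighbour's could differ too, so the bound set beforehand was too weak to exclude this. Shared regulation of tandem gene copies may be another source of the pattern and was not tested, since probe sequences were not analysed here.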
